A study of Mus musculus with 12 samples.

How the data were processed

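The log2 values were used as deposited, in 1 table of 45101 probe sets by 12 arrays; per the submitters' processing notes they were made with Affymetrix Expression Console 1.1. The normalization method is not given in the sources used here. The values ran from 2.427 to 15.07 with array medians of 4.67 to 4.72, the sorted values of any 2 arrays differed by at most 0.253, and 0 pairs of arrays were identical, so they were not normalized again. The lowest correlation between arrays of a group was 0.991 and the highest between unstimulated and stimulated arrays was 0.98. Of the probe sets, 64 were controls and were left out of the tests, 34945 of the 45037 others had 1 gene symbol, and 932 had several and were not used as genes. Each of 18193 genes was represented by its probe set with the highest mean signal, and names ending in x_at or s_at, such as those used for Dcpp3, Tubb2a, Ighm, Tnfrsf21 and Iffo2, mark probe sets that can bind more than 1 transcript. The reference gene table was used only for names and for the order of genes on the chromosomes, and 0 symbols changed through it. Left out were probe sets of several genes from the lists, positions on the chromosomes beyond the order of genes, and any measure of protein.

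Group means of the 12 arrays were fitted with limma 3.58.1 in R 4.3.3, with moderated variances (8 residual and 4.18 prior degrees of freedom). The 5 comparisons were stimulated against unstimulated cells in wild type and in null cells, null against wild type without and with antigen, and the difference of the stimulation effects. A probe set counted as called at an adjusted two-sided p under 0.05 (Benjamini and Hochberg, over 45037 probe sets). The size of the response was tested per mouse by an exact permutation test, whose smallest two-sided p with 3 against 3 mice is 0.1. The probe sets used there rose or fell by at least 1 on average over both genotypes, an average that does not depend on the genotype difference.

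The gene lists and the rule for naming genes were written before the data were examined. Of 23 lists, 21 were tested with camera at a preset correlation of 0.01; protein kinase D genes and sex-linked genes served as checks of the labels. An estimated correlation between the genes of a list, fry, and the mean over all probe sets of a gene were alternatives. In fry the directional p tests whether the genes of a list move on balance one way and the mixed p whether they move in either direction, and neither compares them with other genes. Counts adjusted over the list alone are given where they differ from those over all probe sets. Named in the text are the 3 protein kinase D genes, Il2 and Ifng in each comparison, and the 10 largest rises and falls of wild-type stimulation that went the same way in all 3 mice. For stimulation of null cells those genes and the 5 largest of its own each way are named, and for each genotype comparison the 10 largest called differences each way without overlap of the 3 and 3 values. For the difference of the effects the called genes and the 5 smallest p are named, and for each list up to 4 called members or, where 0 were called, up to 2 with the largest change. Genes named outside this rule are stated as picked out after their values were seen.

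In a self-test 200 of 45037 probe sets of a made-up table with the design and spread of the real one were given a known change. The others had equal means in all groups, while real stimulation changed 29% of probe sets in wild type and 24.8% in null cells. The adjustment was therefore stricter in the self-test, and its shares for stimulation do not carry over to the real comparisons. For stimulation in wild type, changes of 0.5, 1 and 2 were recovered in 27%, 88% and 98% of cases, with 3.57%, 5.38% and 6.67% of calls false. For stimulation in null cells these were 18.5%, 90% and 99.5%, with 11.9%, 7.69% and 2.93% false. For null against wild type they were 18%, 91.5% and 99.5% without antigen (2.7%, 5.18% and 5.24% false) and 25%, 88.5% and 97% with antigen (5.66%, 5.35% and 2.51% false). For the difference of the stimulation effects they were 0%, 63% and 93.5% (0%, 6.67% and 5.56% false), so a difference of 0.5 between the effects could not be seen. In 100 draws with 21 lists each, camera called 0.238% of unchanged lists and called a list shifted by -0.8 in 100 draws. The noise there was drawn independently for each gene, so this rate does not cover lists whose genes correlate. A response ratio of 1 was returned as 0.995 and one of 0.8 as 0.803.

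The pairing of arrays by mouse was taken from the animal numbers in the labels. Deviations from the group means were correlated between each unstimulated array and the stimulated arrays of that genotype. Each unstimulated array correlated more with the stimulated array of its own mouse (0.116 to 0.577) than with that of another mouse (at most 0.129). The closest case was wild-type replicate 2 (0.116 against 0.0831). The stimulated arrays were not checked in the same way. Sex-linked genes gave 1 male of 3 mice in each genotype, with the 2 arrays of each mouse on the same side. The pairing entered as an alternative with the mouse as a fixed block for stimulation and its difference, and as a random block for the genotype comparisons (correlation within a mouse of 0.202). Other alternatives planned were a fit of only the groups compared, quantile normalization, 1 probe set per gene, leaving out each array, a variance trend with robust fitting, array weights, only probe sets above the median level, and a fold threshold. For the response size they were thresholds of 0.5 and 2, medians, probe sets above the median level, and leaving out each mouse.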

Results

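Gene expression was measured on 12 Affymetrix arrays in lymph node cells of P14 mice, whose transgenic T cell receptor recognises a viral peptide (gp33-41) on MHC class I. The cells came from 3 wild-type mice and from 3 mice that lack protein kinase D2 (PKD2, the product of Prkd2), a serine/threonine kinase that is activated downstream of the antigen receptor. For each mouse, 1 array held cells cultured for 4 h without peptide and 1 array held cells cultured for 4 h with peptide at 62.5 ng/ml, which gave 4 groups of 3 arrays. Each array gave a log2 signal for 45037 probe sets besides 64 controls, with array medians between 4.67 and 4.72. The number of arrays limits the precision. Changes below are on the log2 scale with the standard error (SE) of the limma fit (n = 3 arrays per group), and the 5 comparisons were tested two-sided. Adjusted p-values cover all 45037 probe sets, and each gene is represented by its probe set with the highest mean signal.

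Prkd2 was far lower in the PKD2-null cells of both conditions. Its mean signal was 10.17 ± 0.172 (SD, n = 3) in unstimulated wild-type cells and 5.999 ± 0.291 in unstimulated null cells, an 18-fold lower signal (log2 difference -4.17, SE 0.148, adjusted p = 2.7e-08). In stimulated cells the means were 8.328 ± 0.178 in wild type and 5.477 ± 0.12 in null, 7.22-fold lower (-2.85, SE 0.148, adjusted p = 2.5e-06). Of the 4 other probe sets of the gene, those with a high wild-type signal were 36.6-fold and 35.4-fold lower in unstimulated null cells, from null means of 4.78 and 5.127 near the array medians. The weaker ones were 2.05-fold lower (adjusted p = 0.024) and 1.18-fold lower (adjusted p = 0.69, at the lower end of the scale). Prkd3, a paralog, had means of 9.501 ± 0.206 and 9.443 ± 0.133 in unstimulated wild-type and null cells (adjusted p = 0.95), and Prkd1, the remaining paralog, lay near the lower end of the scale in the 4 groups, between 3.546 and 3.9, with no call.

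**Figure D1:**
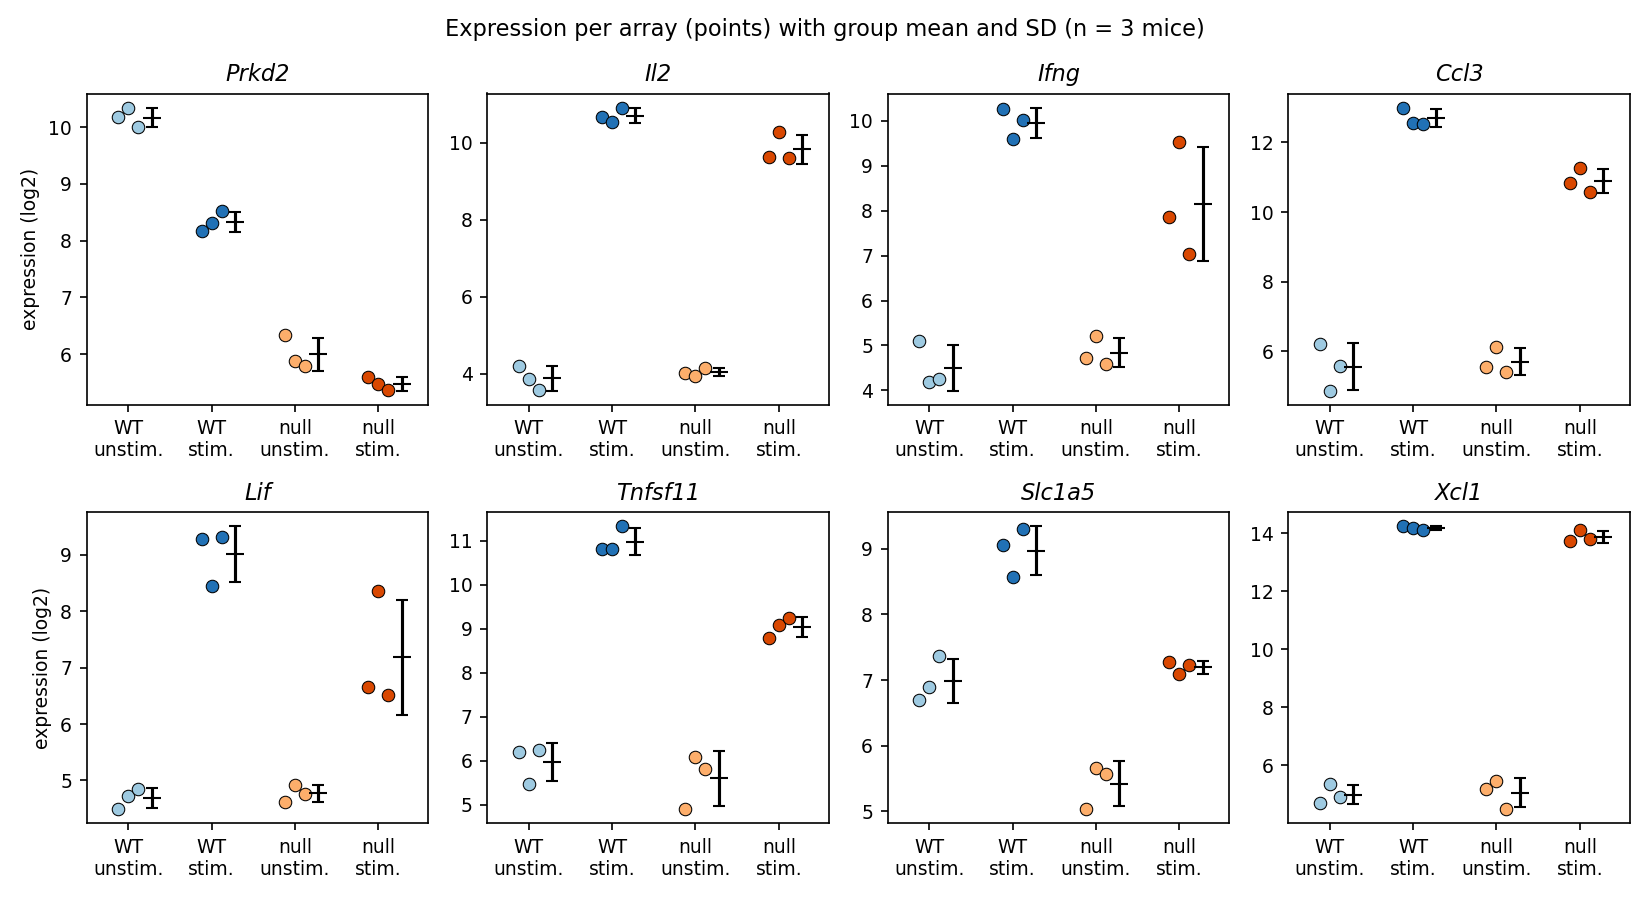
Log2 signal per array for 8 genes in the 4 groups of 3 arrays, with the group mean and SD as bars. Prkd2 was lower in the null arrays of both conditions, and the stimulated means of Ccl3 were 12.7 in wild type and 10.9 in null cells.

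The first comparison asked what antigen does to wild-type cells within 4 h. The single genes with the largest rises included chemokine and cytokine genes. Xcl1, a chemokine that attracts cross-presenting dendritic cells, rose by 9.19 (SE 0.222, adjusted p = 4.1e-10) to 14.18, near the top of the scale. Ccl3, an inflammatory chemokine, rose by 7.14 (SE 0.301), its relative Ccl4 by 6.37 (SE 0.239), and Il2, the T cell growth factor, by 6.82 (SE 0.189, adjusted p = 8.8e-10). Ifng, which encodes interferon gamma, rose by 5.45 (SE 0.483, adjusted p = 2.1e-06). Crtam, an adhesion receptor of class I-restricted T cells, rose by 6.39, the zinc finger gene Hivep3 by 6.24 and Tnfsf14, which encodes the cytokine LIGHT, by 6.01. Tbx21, which encodes T-bet, rose by 5.67 and the receptor gene Cd160 by 5.56 (adjusted p at most 2.7e-07 for these 5 genes). The 10 largest falls included Rflnb, a filamin-binding protein (-3.49, SE 0.229), Pik3ip1, an inhibitor of PI3 kinase (-2.87, SE 0.216), and the repressor Klf3 (-2.82, SE 0.179). They also included S1pr1, the sphingosine 1-phosphate receptor that lets T cells leave lymph nodes (-2.81, SE 0.142, adjusted p = 2.1e-08). The other 6 were Slc6a19 (-3.15), Fam78a (-3.07), Bambi-ps1 (-3.04), Tdrp (-2.91), Mturn (-2.79) and Heatr5a (-2.71), and the 20 genes moved the same way in all 3 mice. The unstimulated wild-type means of Il2 (3.881) and Tnfsf14 (4.198) lay near the lower end of the scale, which limits the size of their rises here and in null cells. In all, 5770 probe sets rose and 7308 fell, 13078 or 29% of those tested, which represented 6458 genes.

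Genes of activation rose as groups in wild-type cells, and genes of resting cells fell (camera over 21 lists). Of 29 early transcription factors, 24 rose and 0 fell (27 rose adjusted over the list alone), with Myc at 4.02, Irf4 at 3.87 and Fosl1 at 3.65. Their median was 1.89 (adjusted p = 8.6e-13, and adjusted p = 0.14 with an estimated correlation). Of 27 cytokines and effector molecules 19 rose, also adjusted over the list alone. The median of this list was 1.90 (adjusted p = 3.2e-09, and adjusted p = 0.14 with an estimated correlation). Of 23 activation receptors 16 rose and 2 fell, also adjusted over the list alone. Tnfrsf9, which encodes the costimulator 4-1BB, rose by 4.77, Il2ra, the IL-2 receptor alpha chain, by 4.51 and Slamf1 by 4.25. The receptors had a median of 1.58 (adjusted p = 7.7e-09, and adjusted p = 0.15 with an estimated correlation).

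Genes of naive and quiescent cells went down in 25 of 28 and up in 1, also adjusted over the list alone, with the glucocorticoid-induced gene Tsc22d3 at -2.50. Their median was -1.47 (adjusted p = 8.6e-13, and adjusted p = 0.14 with an estimated correlation). Negative feedback regulators went both ways, 14 of 27 up and 7 down (16 and 7 adjusted over the list alone). Spry1, an inhibitor of Ras signalling, rose by 5.31, Rgs16 by 3.59 and Cish by 3.10, while Dusp10, a MAP kinase phosphatase, fell by 2.69. The regulators had a median of 0.65 (adjusted p = 0.02, and adjusted p = 0.38 with an estimated correlation).

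Genes for growth rose together in wild-type cells. All 28 ribosome biogenesis genes rose, also adjusted over the list alone, among them Nolc1 (3.05), Polr1b (2.96), Rrp12 (2.89) and Nop16 (2.88). Their median was 2.22 (adjusted p = 5.6e-27, and adjusted p = 0.13 with an estimated correlation). In glycolysis 8 of 15 genes rose, also adjusted over the list alone, led by the hexokinase gene Hk2 (3.44), the lactate transporter gene Slc16a1 (2.39), Pgam1 (1.99) and Ldha (1.48). The glycolysis median was 0.43 (adjusted p = 0.00061, and adjusted p = 0.14 with an estimated correlation). In cholesterol synthesis and uptake 10 of 17 rose (11 up and 1 down adjusted over the list alone), with Cyp51 at 2.68, Idi1 at 2.54, Sqle at 2.22 and Hsd17b7 at 1.92. The cholesterol median was 0.53 (adjusted p = 0.00052, and adjusted p = 0.4 with an estimated correlation). In amino acid supply and ATF4 targets 12 of 21 rose and 4 fell (14 and 4 adjusted over the list alone). Psat1, an enzyme of serine synthesis, rose by 3.16, the transporter gene Slc7a5 by 3.00, and the mitochondrial folate enzyme genes Mthfd2 and Shmt2 by 2.78 and 2.63. These genes had a median of 0.94 (adjusted p = 0.00023, and adjusted p = 0.32 with an estimated correlation).

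Of 29 interferon response genes 16 rose and 2 fell in wild-type cells (19 and 2 adjusted over the list alone). The chemokine genes Cxcl10 and Cxcl9 rose by 4.99 and 2.75 and the GTPase genes Iigp1 and Irgm1 by 3.89 and 3.16. Their median was 0.85 (adjusted p = 0.00032, and adjusted p = 0.56 with an estimated correlation). B cell markers were lower in 8 of 14 and higher in 1 (10 and 1 adjusted over the list alone), with Cd79b at -1.42, Fcrla at -1.40 and Ighm at -1.12. The B cell list had a median of -0.70 (adjusted p = 0.019, and adjusted p = 0.7 with an estimated correlation). The mean level of its genes was 8.822 ± 0.047 (SD, n = 3) without and 8.193 ± 0.0916 with peptide.

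The remaining 10 lists did not pass in wild-type cells. Cell cycle genes went both ways (4 up and 6 down of 29). Ccnd2 rose by 3.04, Cdk4 by 1.64 and Cdk6 by 1.19, and Ccnd3 fell by 1.14. Their median was -0.0425, with a positive mean of 0.0736 and an upward test (adjusted p = 0.83). T cell receptor signalling components had 6 up and 9 down of 22 (7 and 9 adjusted over the list alone), with Zap70 at 2.17, Malt1 at 2.10, Lcp2 at 1.80 and Fyn at 1.33. The median of -0.12 and the downward test differed in sign from the mean of 0.0319 (adjusted p = 0.79). Class IIa histone deacetylases are substrates of protein kinase D and repress MEF2 factors. Of 8 such genes 4 fell: Mef2d (-1.24), Hdac5 (-1.20), Mef2c (-0.99) and Hdac4 (-0.72), with a median of -0.44 (adjusted p = 0.056).

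Single markers of cell types changed in wild-type cells while their lists did not pass. Cd8b1 (-1.38), Ikzf2 (-0.92), Tnfrsf25 (-0.67), Sdc1 (-1.24), Mzb1 (-0.83), Ctss (-0.54), Klrd1 (-1.20) and Pecam1 (-1.48) fell, and Foxp3 (0.86), Zbtb46 (0.47) and Nkg7 (1.56) rose. The adjusted p was 0.2 for CD8 T cells, 0.61 for CD4 T cells, 0.54 for plasma cells, 0.79 for myeloid cells (0 up and 1 down adjusted over the list alone), 0.83 for NK cells and 0.95 for stroma. For stroma the median and test were positive and the mean negative. The erythroid list of 3 genes did not pass either (adjusted p = 0.92), with Alas2 at -0.56 (adjusted p = 0.66, and 0.0025 with the mouse as a block) and Hba-a1 at 0.12, a positive median and test and a negative mean. The difference between 3′ and 5′ actin control probe sets, a sign of RNA quality, was 0.278 ± 0.0233 (SD, n = 3) without and 0.211 ± 0.0286 with peptide in wild type. In null cells it was 0.278 ± 0.0718 and 0.2 ± 0.0214.

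The same question was asked in PKD2-null cells. The genes that led the wild-type response also rose without PKD2: Xcl1 by 8.83 (SE 0.222, adjusted p = 6.6e-10), Il2 by 5.79 (SE 0.189, adjusted p = 3.9e-09), Ccl3 by 5.20 (SE 0.301, adjusted p = 1.2e-07) and Ifng by 3.31 (SE 0.483, adjusted p = 0.00019). Hivep3 rose by 6.06, Tnfsf14 by 5.79, Crtam by 5.72, Ccl4 by 5.55, Cd160 by 5.52 and Tbx21 by 5.23. The 10 genes with the largest falls in wild type fell here too, from Bambi-ps1 at -2.19 to Rflnb at -3.29, S1pr1 by 2.34 and Klf3 by 2.51. Il7r, the IL-7 receptor alpha chain that naive cells need for survival, joined the 5 largest falls at -2.59 (SE 0.195, adjusted p = 9.7e-07; -2.41 in wild type). In all, 4957 probe sets rose and 6213 fell, 11170 or 24.8% of those tested, which represented 5724 genes. Of the wild-type calls, 4271 rises (74%) and 5436 falls (74.4%) were also called in null cells, against 635.1 and 1008 if the calls were independent, and 5 probe sets were called in opposite directions.

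The same activation lists passed in null cells. Early transcription factors rose in 22 of 29, also adjusted over the list alone (Myc 3.60, Nr4a2 3.35, Irf4 3.15). Their median was 1.34 (adjusted p = 7.9e-13, and adjusted p = 0.15 with an estimated correlation). Cytokines and effector molecules rose in 16 of 27, also adjusted over the list alone, with a median of 1.62 (adjusted p = 7.9e-09, and adjusted p = 0.15 with an estimated correlation). Activation receptors rose in 16 and fell in 2 of 23 (17 and 2 adjusted over the list alone), with Il2ra at 3.99, Tnfrsf9 at 3.88 and Slamf1 at 3.57. The receptors had a median of 1.11 (adjusted p = 7.9e-09, and adjusted p = 0.15 with an estimated correlation). Naive and quiescence genes fell in 24 and rose in 1 of 28 (25 and 1 adjusted over the list alone). The median of this list was -1.48 (adjusted p = 2.1e-12, and adjusted p = 0.15 with an estimated correlation). Negative feedback regulators rose in 12 and fell in 6 of 27, also adjusted over the list alone (Spry1 4.76, Rgs16 3.41, Cish 2.63, Dusp10 -2.39). The regulators had a median of 0.33 (adjusted p = 0.0071, and adjusted p = 0.3 with an estimated correlation).

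Growth genes rose in null cells as well. All 28 ribosome biogenesis genes did, also adjusted over the list alone (Nolc1 2.59, Polr1b 2.54, Rrp12 2.53, Gnl3 2.52). Their median was 1.92 (adjusted p = 3.6e-31, and adjusted p = 0.087 with an estimated correlation). Glycolysis genes rose in 7 and fell in 1 of 15, also adjusted over the list alone (Hk2 2.57, Slc16a1 2.40). The glycolysis median was 0.19 (adjusted p = 0.0014, and adjusted p = 0.15 with an estimated correlation). Cholesterol genes rose in 11 of 17 (11 up and 2 down adjusted over the list alone), with Cyp51 at 2.17 and Idi1 at 2.04. The cholesterol median was 0.70 (adjusted p = 0.00014, and adjusted p = 0.37 with an estimated correlation). Amino acid and ATF4 genes rose in 12 of 21 (12 up and 2 down adjusted over the list alone), with Slc7a5 at 2.77, Psat1 at 2.49 and Slc7a1 at 2.34. These genes had a median of 0.76 (adjusted p = 8e-06, and adjusted p = 0.22 with an estimated correlation). B cell markers fell in 5 of 14 (10 adjusted over the list alone), with Fcrla at -1.16, Cd79b at -0.88 and Blnk at -0.76. The B cell list had a median of -0.62 (adjusted p = 0.0074, and adjusted p = 0.71 with an estimated correlation), and its mean level went from 9.495 ± 0.408 (SD, n = 3) to 8.889 ± 0.412.

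The interferon response list did not pass in null cells. Of its 29 genes 6 rose and 2 fell, with Cxcl10 at 3.86, Iigp1 at 2.42, Irgm1 at 2.37 and Cxcl9 at 2.10, and its median was 0.19 (adjusted p = 0.072). With the mouse as a block this list passed (adjusted p = 0.0044). Plasma cell markers, of which Sdc1 (-1.02), Mzb1 (-0.88) and Xbp1 (-0.46) fell, gave an adjusted p of 0.16 without and 0.036 with the block. Myeloid markers, of which Ctss (-0.60) fell, gave an adjusted p of 0.11 without and 0.0067 with it. Cell cycle genes (4 up and 7 down of 29, 4 and 9 adjusted over the list alone, Ccnd2 at 3.25, Cdk4 at 1.36) gave 0.55 and T cell receptor signalling genes (6 up and 8 down of 22, 8 and 8 adjusted over the list alone, Lcp2 at 2.19, Zap70 at 2.16) gave 0.64. Deacetylase and MEF2 genes (3 of 8 down, 1 up and 3 down adjusted over the list alone, Hdac5 at -1.11, Mef2c at -0.81, Mef2d at -0.68) gave 0.24. CD8 markers (Cd8b1 -1.11) gave 0.81, with a positive median and a negative mean and test. CD4 markers (Tnfrsf25 -0.80, Foxp3 0.67) gave 0.64 and NK markers (Nkg7 1.47, Klrd1 -1.12) 0.62. Stromal markers (Pecam1 -1.52, Pdpn 0.34) gave 1, with a positive median and a negative mean and test, and erythroid markers (Alas2 -0.17, Slc4a1 0.12) 0.85, with a negative median and mean and a positive test.

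The third comparison asked whether PKD2-null cells differ before antigen is added. Besides Prkd2, 7 genes differed, and for each the 3 null values lay apart from the 3 wild-type values. Slc1a5, which encodes the glutamine transporter ASCT2, was 2.95-fold lower in null cells (-1.56, SE 0.214, adjusted p = 0.027). Neto2, an auxiliary subunit of kainate receptors, was lower as well (-0.995, SE 0.146, adjusted p = 0.049), as were the tubulin gene Tubb2a (-0.85, SE 0.103, adjusted p = 0.013), the junction protein gene Pkp4 (-0.73, SE 0.0773, adjusted p = 0.0065) and Rundc3b (-0.62, SE 0.0829, adjusted p = 0.024). Ifi30, a lysosomal thiol reductase of antigen-presenting cells, was higher by 1.08 (SE 0.124, adjusted p = 0.011) and Plekho1, which binds casein kinase 2, by 0.72 (SE 0.0957, adjusted p = 0.024). Il2 (0.16, adjusted p = 0.87) and Ifng (0.33, adjusted p = 0.9) did not differ, with means under 5 in both genotypes. In all, 7 probe sets were higher and 10 lower, which represented 8 genes, and 4014 had an unadjusted p under 0.05 against 2252 by chance.

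Markers of B cells were higher as a group in unstimulated null cells, although 0 of 14 passed singly in limma (12 adjusted over the list alone). Fcrla had a difference of 1.01 and Ighm of 1.01, and the list median was 0.65 (adjusted p = 2.1e-11, and adjusted p = 0.28 with an estimated correlation). Their mean level was 8.822 ± 0.047 (SD, n = 3) in wild type and 9.495 ± 0.408 in null cells, highest at 9.964 in null replicate 2. Plasma cell markers were higher as a group (Sdc1 1.05, Jchain 1.04), with 3 adjusted over the list alone. Their median was 0.86 (adjusted p = 0.00084, and adjusted p = 0.35 with an estimated correlation). Myeloid markers (S100a9 0.995, S100a8 0.99) had a median of 0.27 (adjusted p = 0.0048, and adjusted p = 0.76 with an estimated correlation). The test of the 3 erythroid markers rested on Alas2 (-2.82, not called), the 1 gene lower adjusted over the list alone, while Slc4a1 (-0.20) and Hba-a1 (-0.0789) lay near the lower end of the scale. The erythroid median was -0.20 (adjusted p = 0.017, and adjusted p = 0.26 with an estimated correlation).

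Proliferation and sterol genes were also higher as groups before antigen, with 0 members called in limma. Cell cycle genes (Ccna2 1.31, Mki67 1.28) had 13 of 29 higher adjusted over the list alone. Their mean level in null replicates 1 to 3 was 7.453, 7.715 and 7.395, highest in the replicate that was also highest in B cell markers (9.299, 9.964 and 9.221). Their median was 0.25 (adjusted p = 8.8e-09, and adjusted p = 0.26 with an estimated correlation). Cholesterol genes (Sqle 0.66, Msmo1 0.61) had 8 of 17 higher adjusted over the list alone. The cholesterol median was 0.34 (adjusted p = 8.8e-09, and adjusted p = 0.28 with an estimated correlation). Ribosome biogenesis genes (Utp20 0.41, Mybbp1a 0.37) had a median of 0.21 (adjusted p = 1.4e-07, and adjusted p = 0.35 with an estimated correlation). Their level was also highest in null replicate 2 (9.057, 9.22 and 8.955). Interferon response genes (Iigp1 -1.22, Rsad2 -1.0) were lower as a group, 2 of 29 adjusted over the list alone. Their median was -0.15 (adjusted p = 0.0058, and adjusted p = 0.85 with an estimated correlation). With the mean of all probe sets of each gene this list did not pass (adjusted p = 0.092). In amino acid supply and ATF4 targets, Slc1a5 was the 1 gene called of 21 (adjusted p = 0.59 for the list). For the myeloid and ribosome lists 0 members passed adjusted over the list alone.

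In the other lists 0 members passed in unstimulated cells in limma. Adjusted over the list alone, 4 activation receptors were higher and 1 lower, 1 early transcription factor was higher and 1 lower, and 1 NK marker was lower. By that count 1 gene each was higher among naive and quiescence, deacetylase and MEF2, and T cell receptor signalling genes. Early transcription factors (Egr1 0.93, Egr2 0.62) gave a list adjusted p of 0.67, cytokines (Gzmc 0.60, Tnfsf8 0.56) 0.61 and activation receptors (Slamf7 0.86, Icos 0.59) 0.063. Negative feedback regulators (Dusp6 0.66, Ubash3a -0.41) gave 0.54, glycolysis genes (Tpi1 0.39, Hk2 0.30) 0.76 and T cell receptor signalling genes (Prkcb 0.40, Fyn 0.31) 0.54. Naive and quiescence genes (Itga6 0.78, Tob1 -0.30) gave 0.87 and deacetylases and MEF2 (Mef2b 0.69, Mef2c 0.56) 0.96, both with a negative median and test and a positive mean. CD8 markers (Cd8b1 -0.19, Cd8a -0.18) gave 0.59, CD4 markers (Foxp3 0.54, Zbtb7b 0.20) 0.76 and NK markers (Klrd1 -1.0, Klrg1 0.47) 0.21. Stromal markers (Glycam1 0.67, Madcam1 0.23) gave 0.96, with a positive median and mean and a negative test.

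Transcripts of salivary glands differed between arrays already without antigen. Dcpp3, a secreted protein of demilune and parotid cells, lay between 11.82 and 14.61 in wild-type arrays and between 6.234 and 9.209 in null arrays. Its difference in unstimulated cells was -5.87 (adjusted p = 0.059, and 0.042 with the mouse as a block). With that block, 44 probe sets were called (19 higher, 25 lower), and the NK receptor gene Klrd1 had an adjusted p of 0.045, against 0.063 without it. The count of 17 was 3 without wild-type unstimulated replicate 3, and 6, 27 and 11 without null unstimulated replicates 1, 2 and 3. It was 5 without the 3 arrays richest in the epithelial transcript Krt18, an alternative chosen after the values were seen.

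The fourth comparison asked how null and wild-type cells differ 4 h after antigen. Of 27 cytokine and effector genes 6 were lower in null cells, among them Ccl3, which was 3.49-fold lower (-1.80, SE 0.301, adjusted p = 0.018), and Tnfsf11, which encodes RANK ligand (-1.94, SE 0.288, adjusted p = 0.011). The cytokine genes Lif (-1.84, SE 0.389, adjusted p = 0.046) and Il3 (-2.14, SE 0.444, adjusted p = 0.043) were others. For Il3 the wild-type values were 4.926, 4.685 and 7.077, and without replicate 3 the difference was -1.38. Outside that list, F3, the tissue factor that starts coagulation, was lower (-2.13, SE 0.255, adjusted p = 0.0035). The null means of Il3 and F3, 3.424 and 3.5, lay at the lower end of the scale, which limits their folds. Slc1a5 stayed lower with antigen (-1.77, SE 0.214, adjusted p = 0.0037), as did Prkd2. Higher in null cells were Ccnb1ip1, which acts in meiotic crossover (2.44, SE 0.165, adjusted p = 4.3e-05), the receptor gene Tnfrsf19 (1.62, SE 0.16, adjusted p = 0.0012), and Pgap1, which remodels GPI anchors (1.50, SE 0.114, adjusted p = 0.00013). Also higher were Marchf1 (1.53), which removes MHC class II from the cell surface, the cannabinoid receptor gene Cnr2 (1.52), Inpp4b (1.46), a lipid phosphatase, the homeobox gene Hhex (1.44), Rpl39l (1.41), Celsr1 (1.36) and the immunoglobulin gene Ighm (1.45, SE 0.277, adjusted p = 0.031). The wild-type means of Ccnb1ip1 (3.696), Rpl39l (4.043) and Tnfrsf19 (4.325) lay at or near the lower end of the scale, which limits their differences. In stimulated null replicates 1 to 3, Marchf1 (6.227, 6.486 and 6.121), Hhex (8.111, 8.51 and 7.795) and Ighm (12.1, 13.2 and 12.2) were highest in replicate 2. So were B cell markers (8.69, 9.362 and 8.614), while Cnr2 (6.651, 6.163 and 6.099) and the other higher genes named were not. Whether a larger share of B cells gave these differences was not tested. For all genes named so far in this comparison the 3 null values lay apart from the 3 wild-type values. In all, 360 probe sets were higher and 171 lower in null cells, 531 that represented 298 genes, and 6 of the higher and 7 of the lower ones were also called without antigen, against 0.056 and 0.038 if independent. Both comparisons used cells of the same mice, so their calls are not independent.

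The cytokines best known from this response differed in size. Il2 in stimulated null cells differed by -0.87 (SE 0.189), with an adjusted p of 0.05 that lay just above the threshold before rounding, so it was not called. Ifng differed by -1.81 (SE 0.483, adjusted p = 0.1) and Ccl4 by -0.95 (adjusted p = 0.085), neither called. Xcl1 (-0.29), Tnfsf14 (-0.16), Cd160 (-0.12), Crtam (0.25) and Tbx21 (-0.36) were not called either, with adjusted p between 0.57 and 0.85. Gzmb and Gzmc, granzymes of the cytokine list that were picked out after their values were seen, differed by -1.76 and -1.27 (adjusted p = 0.038 and 0.025). The null mean of Gzmc, 4.145, lay near the lower end of the scale, which limits its difference.

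**Figure D2:**
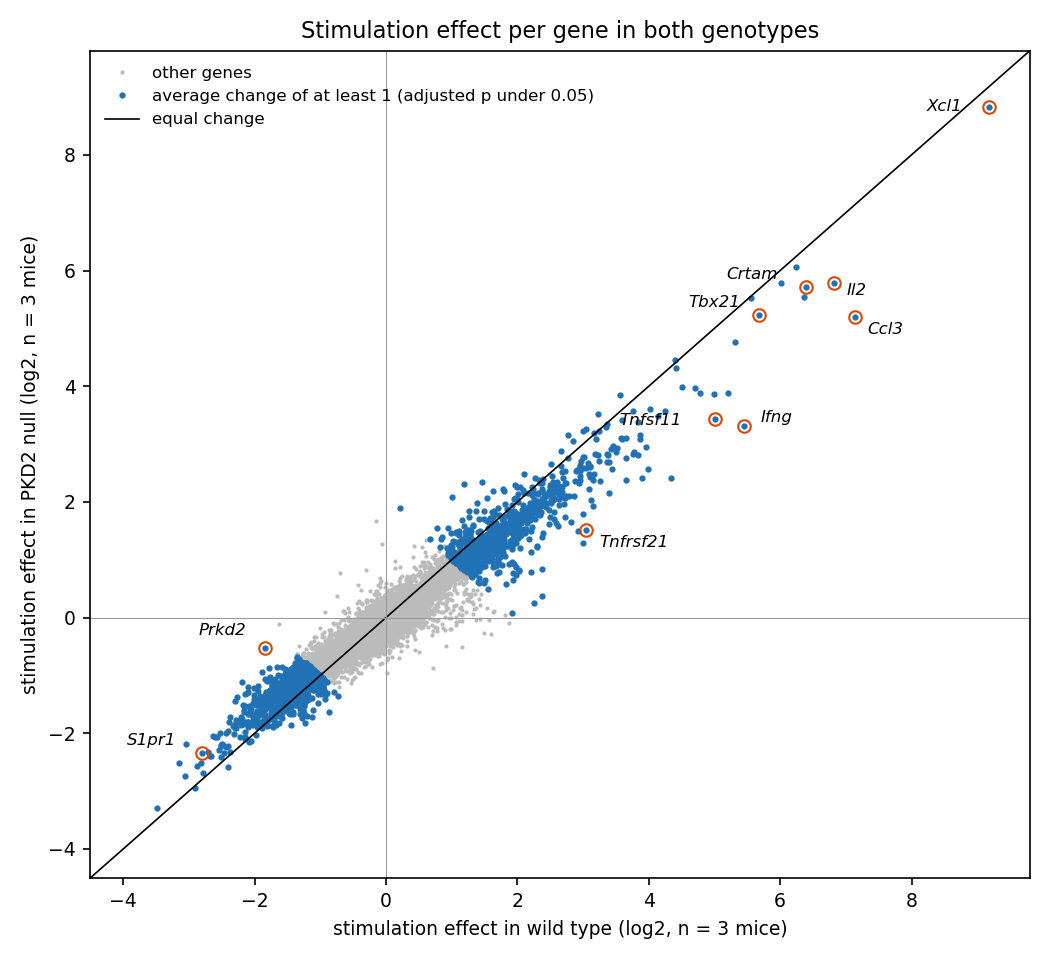
Stimulation effect per gene (log2) in wild-type cells on the horizontal axis and in PKD2-null cells on the vertical axis, with the line of equal change. Xcl1 lies near the line at 9.19 and 8.83, and Ccl3 (7.14 and 5.20) and Ifng (5.45 and 3.31) lie below it.

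Grouped by list, interferon response genes were lower in stimulated null cells, with 2 of 29 called (19 adjusted over the list alone). Oasl2 differed by -1.73 (SE 0.259, adjusted p = 0.011), with a null mean of 3.715 at the lower end of the scale, and Xaf1, which promotes apoptosis, by -1.45 (SE 0.163, adjusted p = 0.0024). Their median was -0.82 (adjusted p = 3.6e-11, and adjusted p = 0.43 with an estimated correlation). The mean level of the list was 7.523, 8.14 and 7.136 in the null replicates and 8.468, 8.273 and 8.515 in wild type, so replicates 1 and 3 carried most of the difference. Cytokines and effector molecules were lower in 6 of 27 (9 adjusted over the list alone). The median of this list was -0.15 (adjusted p = 0.0043, and adjusted p = 0.43 with an estimated correlation). Early transcription factors were lower in 2 of 29, also adjusted over the list alone. The stress factor gene Atf3 differed by -1.60 (SE 0.292, adjusted p = 0.027) and Fosl1, an AP-1 subunit, by -0.85 (adjusted p = 0.046), and the list median was -0.24 (adjusted p = 0.0029, and adjusted p = 0.43 with an estimated correlation).

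Genes of naive and quiescent cells were higher in stimulated null cells in 3 of 28 (6 adjusted over the list alone). S1pr1 differed by 0.67 (adjusted p = 0.046), Foxp1 by 0.46 (adjusted p = 0.048) and Bach2 by 0.43 (adjusted p = 0.048, and 0.051 with the mouse as a block). Their median was 0.22 (adjusted p = 0.00061, and adjusted p = 0.43 with an estimated correlation). Of the class IIa deacetylase and MEF2 genes, Mef2d was higher by 0.52 (SE 0.0947, adjusted p = 0.027), and 2 of 8 were adjusted over the list alone. The list median was 0.17 (adjusted p = 0.012, and adjusted p = 0.42 with an estimated correlation). Of T cell receptor signalling genes Prkcb (0.63) and Nfatc2 (0.57) were higher, 4 of 22 adjusted over the list alone. These genes had a median of 0.13 (adjusted p = 0.0026, and adjusted p = 0.43 with an estimated correlation).

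B cell markers were higher in stimulated null cells in 3 of 14 (10 adjusted over the list alone), Ighm, Fcrla at 1.25 and Cd79b at 1.19. The B cell list had a median of 0.70 (adjusted p = 2.1e-08, and adjusted p = 0.43 with an estimated correlation). Their mean level was 8.193 ± 0.0916 (SD, n = 3) in wild type and 8.889 ± 0.412 in null cells, and that of the interferon response list was 8.419 ± 0.129 and 7.6 ± 0.506. Cholesterol genes (Hmgcs1 0.62, Msmo1 0.48) were higher as a group, with a median of 0.27 (adjusted p = 0.00018, and adjusted p = 0.43 with an estimated correlation). Cell cycle genes (Mki67 0.72, Rrm2 0.69) were too, with a median of 0.23 (adjusted p = 0.0016, and adjusted p = 0.43 with an estimated correlation). Ribosome biogenesis genes (Nop16 -0.36, Rrp9 -0.21) were lower as a group, with a median of -0.12 (adjusted p = 0.014, and adjusted p = 0.53 with an estimated correlation). In these 3 lists 0 members were called in limma over all probe sets or adjusted over the list alone.

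The other 11 lists did not pass with antigen. Among activation receptors Il2ra was lower (-0.63, adjusted p = 0.038), the 1 call of 23, and the list gave 0.09. Negative feedback regulators gave 0.42, with Spry2 lower (-1.16, adjusted p = 0.049; 3 up and 5 down adjusted over the list alone). Amino acid and ATF4 genes gave 0.7, where the stress genes Ddit3 (0.53) and Ddit4 (0.80) were higher and Slc1a5 lower. Glycolysis genes gave 0.12 (Hk2 -0.57, Hk1 -0.51, not called; 1 up and 2 down adjusted over the list alone). Plasma cell markers gave 0.069 (Sdc1 1.26, adjusted p = 0.011, and 2 higher adjusted over the list alone) and NK markers 0.086 (Klrd1 -0.92, adjusted p = 0.027). CD8 markers (Cd8a 0.30, Cd3e 0.29) gave 0.082, CD4 markers (Foxp3 0.34, Ikzf2 0.30) 0.33 and myeloid markers (S100a9 0.70, S100a8 0.52) 0.62. Stromal (Glycam1 -0.34, Col3a1 -0.21) and erythroid markers (Alas2 -2.43, Hba-a1 -0.23) gave 0.95 and 0.059, with 2 erythroid genes lower adjusted over the list alone.

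**Figure D3:**
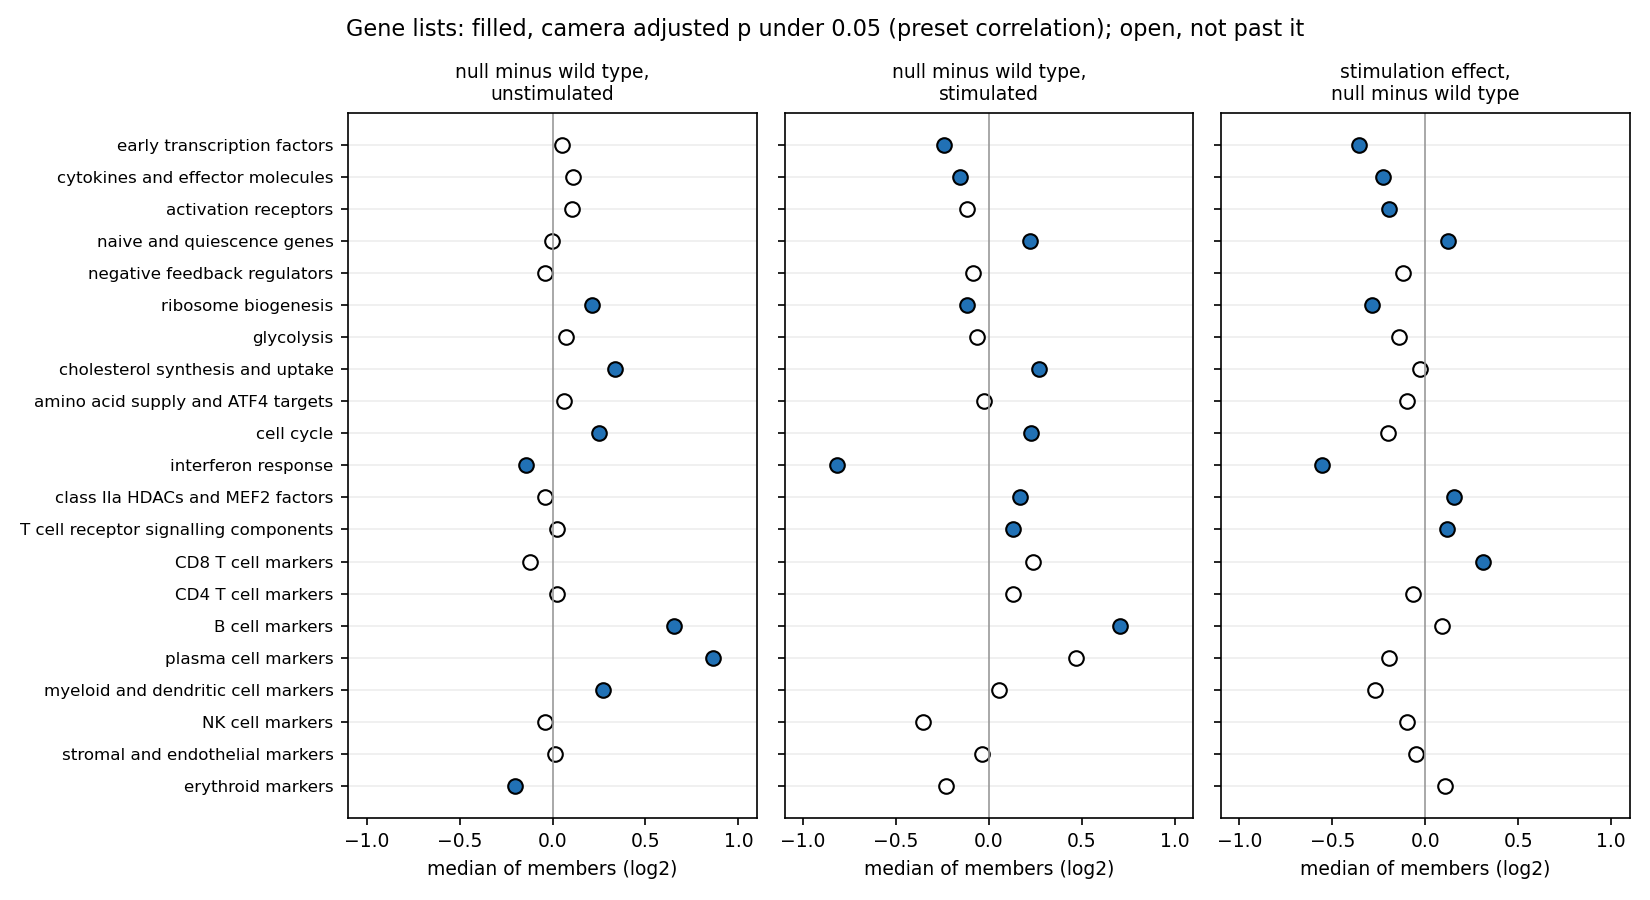
Median log2 difference of each gene list between null and wild type in unstimulated cells, in stimulated cells, and in the stimulation effect, with filled points where camera passed at the preset correlation. Interferon response genes have the lowest medians with antigen (-0.82) and in the stimulation effect (-0.56).

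The largest differences with antigen were in transcripts that salivary glands secrete: Scgb2b27 (-6.50, SE 1.35, adjusted p = 0.043), Dcpp3 (-6.15, SE 0.927, adjusted p = 0.011) and A2ml1, a protease inhibitor (-5.68, SE 1.07, adjusted p = 0.03). Scgb2b27 and A2ml1 had null means of 3.678 and 3.868, at the lower end of the scale. The epithelial keratin gene Krt18 stood at 10.1 in wild-type unstimulated replicate 3 and at 11.4 and 10.2 in wild-type stimulated replicates 2 and 3, against 6.5 to 6.77 in the other wild-type arrays and 3.97 to 5.12 in null arrays. Of the 531 probe sets called, 452 responded to antigen on average over both genotypes. Among those induced 123 were lower and 27 higher in null cells, and among those repressed 289 were higher and 13 lower. These are differences in level and not in response, and Slc1a5, Ighm (1.01) and Fcrla (1.01) differed the same way without antigen, where Slc1a5 was called. Marchf1, Inpp4b, Rpl39l and Hhex were also higher without antigen, though not called. Their unstimulated means were 7.35, 7.571, 4.813 and 9.203 in null cells and 6.202, 6.591, 4.124 and 8.545 in wild type. Ccnb1ip1, Pgap1, Cnr2 and Celsr1 were higher without antigen too and not called. Their unstimulated means were 4.467, 7.361, 7.422 and 5.978 in null cells and 3.842, 6.807, 6.967 and 5.739 in wild type. Xaf1 was already lower without antigen, also not called (7.274 in null cells and 8.078 in wild type). Tnfrsf19 was not higher without antigen (4.046 in null cells and 4.105 in wild type). The count of 531 was 181 and 159 without wild-type stimulated replicates 2 and 3, and 75 and 172 without null stimulated replicates 1 and 3. It was 11 without the 3 arrays richest in Krt18, which leaves 1 stimulated wild-type array that is assumed to vary like the other groups. Normalizing the arrays again left 262 higher and 199 lower.

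**Figure D4:**
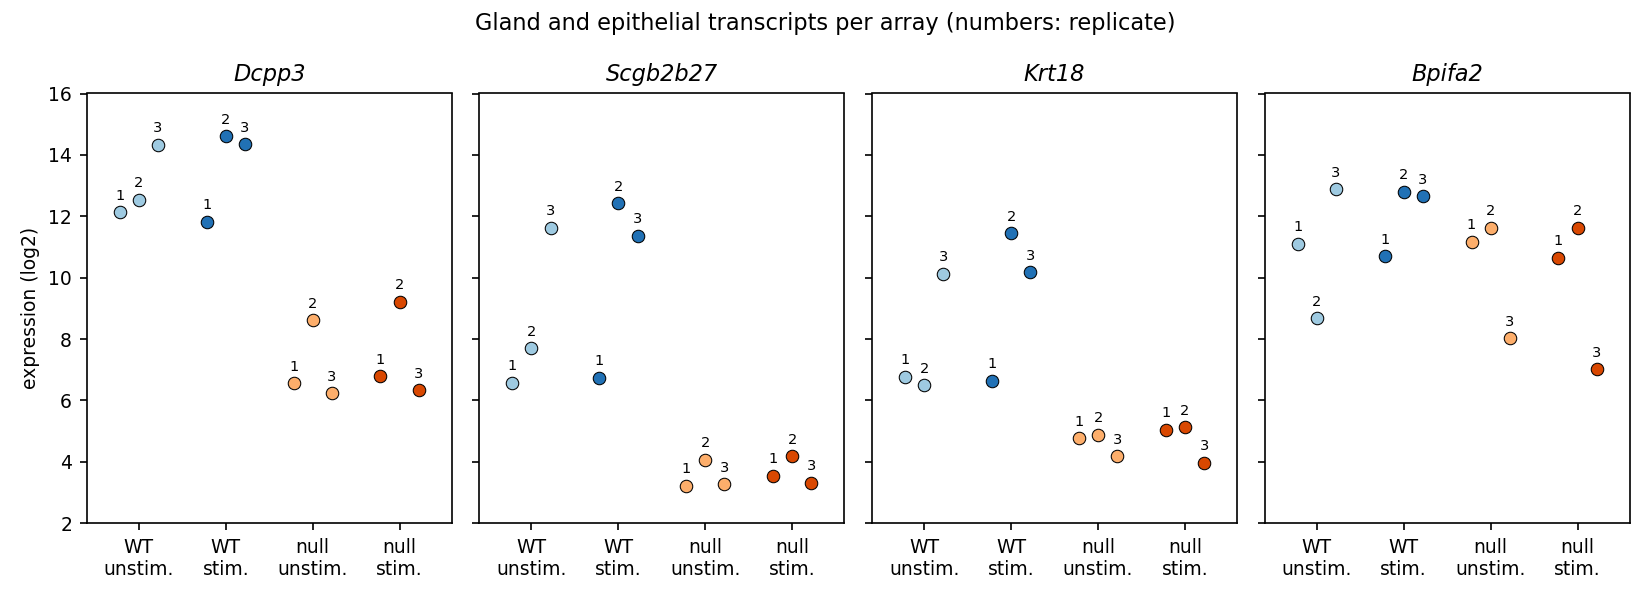
Log2 signal per array of 4 transcripts of gland tissue in the 4 groups, with replicate numbers at the points. Krt18 was between 10.1 and 11.4 in 3 wild-type arrays, and Bpifa2 was present in arrays of both genotypes.

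The last comparison asked whether the response to antigen itself differs between genotypes. The 1 gene called was Tnfrsf21, which encodes death receptor 6: it rose by 3.05 in wild-type and by 1.52 in null cells. The difference was -1.53 (SE 0.172, adjusted p = 0.05, just under the threshold before rounding, and 0.033 with the mouse as a block). Its unstimulated means, 3.964 and 4.24, lay near the lower end of the scale, which limits that difference, as it does for Il2. Among the probe sets that represent genes, the next smallest p-values did not pass. Ccnb1ip1 changed by -0.15 in wild type and 1.67 in null cells (difference 1.82, SE 0.234, adjusted p = 0.081), and Tnfrsf19 by 0.22 and 1.90 (1.68, adjusted p = 0.081). Likewise, Iffo2 changed by -0.05 and 1.28 (1.33, adjusted p = 0.13) and Nbn, a DNA repair gene, by 1.92 and 1.25 (-0.67, adjusted p = 0.13). Other probe sets of Tnfsf11 and Tnfrsf19 also had an adjusted p of 0.081. That of Tnfsf11 rose by 4.31 in wild-type and 2.35 in null cells (-1.95, and adjusted p = 0.0097 with the mouse as a block). That of Tnfrsf19 rose by 0.382 and 3.3 (2.91, and 0.034 with the block). The probe set that represents Tnfsf11 differed by -1.58 (adjusted p = 0.46, and 0.066 with the block). Ccnb1ip1 and Tnfrsf19 had unstimulated means near the lower end of the scale too (3.842 and 4.105 in wild type, 4.467 and 4.046 in null cells), which limits their differences. The effects on Ifng differed by -2.14 (SE 0.682, adjusted p = 0.55), on Ccl3 by -1.94 (SE 0.426, adjusted p = 0.41) and on Il2 by -1.03 (SE 0.268, adjusted p = 0.46). Prkd2 itself fell with antigen by 1.84 in wild-type cells (adjusted p = 9.4e-07) and by 0.52 in null cells (adjusted p = 0.019), a difference of 1.32 (adjusted p = 0.16). Over all probe sets 3209 had an unadjusted p under 0.05 against 2252 by chance.

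With the mouse as a block, which uses the pairing of the 2 arrays of each mouse, 43 probe sets passed, 34 with a lower and 9 with a higher effect in null cells. Of the genes named by rule these included Ccl3 (adjusted p = 0.034), Slamf7, an activation receptor (-1.42, adjusted p = 0.049, and 0.23 without the block), and the interferon regulatory factor Irf8 (-1.22, adjusted p = 0.034, and 0.54 without). Others were Ccnb1ip1 (adjusted p = 0.016), Tnfrsf19 (0.049) and Celsr1 (1.12, adjusted p = 0.043, and 0.41 without). Prkd2 passed too (0.046), but its low signal in null cells left less room to fall. Part of the Slamf7 and Irf8 differences lay in higher null levels before antigen (5.653 and 9.401, against 4.797 and 8.86 in wild type). Gzmb (-1.71, 0.51 without the block) and Gzmc (-1.88, 0.23 without) also passed with the block and were picked out after their values were seen. The unstimulated wild-type mean of Gzmc, 3.826, lay near the lower end of the scale, which limits its difference. Without the block, the count of 1 was 0 without wild-type unstimulated replicates 1 or 2, wild-type stimulated replicate 3, or null unstimulated replicates 1 or 3 or stimulated replicate 1. It was 2 without wild-type stimulated replicates 1 or 2, 4 and 13 without null stimulated replicates 3 and 2, and 0 without the 3 arrays richest in Krt18.

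As groups, ribosome biogenesis genes rose less in null cells: all 28 had a lower effect, with Nop16 at -0.53 and Nolc1 at -0.46. Their median was -0.29 (adjusted p = 1.3e-10, and adjusted p = 0.51 with an estimated correlation). Much of it came from their higher level in null cells before antigen (median 0.21), as the stimulated levels differed by a median of -0.12. Interferon response genes had a lower effect in 25 of 29, with Iigp1 at -1.47 and Oasl2 at -1.40. The interferon median was -0.56 (adjusted p = 8.6e-06, and adjusted p = 0.51 with an estimated correlation). Cytokines and effector molecules (Ifng, and Il3, whose unstimulated values at the lower end of the scale allow no exact difference) had 8 of 27 lower adjusted over the list alone. The median of this list was -0.23 (adjusted p = 0.00052, and adjusted p = 0.51 with an estimated correlation). Early transcription factors (Fosl1 -1.28, Irf8 -1.22) had 1 of 29 lower adjusted over the list alone, with a median of -0.36 (adjusted p = 0.00081, and adjusted p = 0.51 with an estimated correlation). Activation receptors (Slamf7, and Cd44 at -0.89) had 2 of 23 lower adjusted over the list alone. The receptors had a median of -0.20 (adjusted p = 0.0013, and adjusted p = 0.51 with an estimated correlation). Part of it lay before antigen: the receptor median, null minus wild type, was 0.11 without and -0.12 with antigen, neither past camera (adjusted p = 0.063 and 0.09). Cd44 also started higher in null cells (9.515 against 9.143 in wild type).

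Lists with effects higher in null cells held resting and signalling genes. Naive and quiescence genes (Foxp1 0.47, Cdkn1b 0.47) had a median of 0.12 (adjusted p = 0.00052, and adjusted p = 0.51 with an estimated correlation). The medians of their change with antigen were alike, -1.47 in wild-type and -1.48 in null cells. Deacetylases and MEF2 (Mef2d 0.56, Mef2b -0.41) had 1 of 8 higher adjusted over the list alone, with a median of 0.15 (adjusted p = 0.018, and adjusted p = 0.48 with an estimated correlation). T cell receptor signalling genes (Cd3g 0.61, Malt1 -0.56) had a median of 0.12 (adjusted p = 0.018, and adjusted p = 0.59 with an estimated correlation). CD8 markers (Cd8a 0.48, Cd3e 0.35) had a median of 0.31 (adjusted p = 0.034, and adjusted p = 0.51 with an estimated correlation). With the mean of all probe sets of each gene, neither the deacetylase and MEF2 list nor the CD8 list passed (adjusted p = 0.067 and 0.087). In these 9 lists 0 members were called in limma over all probe sets, and 0 adjusted over the list alone where no number is given.

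Cell cycle genes (median -0.20, Aurkb -0.73, Ccna2 -0.66) did not pass (adjusted p = 0.085) but did with the mouse as a block (0.013). Myeloid markers (median -0.27, Cd14 -0.69, S100a8 -0.47) did not pass either (adjusted p = 0.06) and did with the block (0.0012). The other 10 lists did not pass. Glycolysis genes (Hk2 -0.87, Pgam1 -0.44) gave an adjusted p of 0.097, cholesterol genes (Cyp51 -0.51, Idi1 -0.49) 0.44 and amino acid and ATF4 genes (Asns -0.79, Mthfd2 -0.69, and 1 gene higher adjusted over the list alone) 0.44. Negative feedback regulators (Spry2 -1.02, Rgs1 -0.91) gave 0.92, B cell markers (Fcer2a -0.77, Cd79b 0.53) 0.82 and plasma cell markers (Prdm1 -0.67, Xbp1 -0.25) 0.44. CD4 markers (Ikzf2 0.46, Foxp3 -0.20) gave 0.77, with a negative median and a positive mean and test. NK (Klrk1 -0.41, Klrg1 -0.35), stromal (Glycam1 -1.01, Pdpn 0.23) and erythroid markers (Alas2 0.39, Hba-a1 -0.15) gave 0.77, 0.94 and 0.92.

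The size of the whole response was compared per mouse. The 1716 probe sets that rose by at least 1 on average over both genotypes rose by a mean of 1.80 ± 0.0607 (SD, n = 3 mice) in wild-type and 1.54 ± 0.117 in null cells, a ratio of 0.857. Each wild-type mouse (1.86, 1.74 and 1.8) lay above each null mouse (1.59, 1.41 and 1.62). The exact permutation test gave a two-sided p of 0.1, the smallest that 3 against 3 mice allow, so it cannot pass 0.05. The 1647 probe sets that fell did so by 1.48 ± 0.15 and 1.23 ± 0.168 on average, a ratio of 0.834 (exact two-sided permutation p = 0.2). Of the 59 genes that rose by at least 3 on average, 53 rose less and 6 rose more in null cells, with differences from -2.14 for Ifng to 0.30 for Lta, a lymphotoxin gene, and a median of -0.55. The tumour necrosis factor gene Tnf rose by 4.40 and 4.45 (these genes were picked out after their values were seen).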

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

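Of the tests below, both tests of the smaller response of null cells were written after that result was seen, and the splits of the samples were planned.

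Results for the difference of the stimulation effects between genotypes were as follows. Tnfrsf21 had a difference of the stimulation effects of -1.53 (adjusted p = 0.05, just under the threshold before rounding). The list medians of that difference were -0.357 for early transcription factors, -0.227 for cytokines and effector molecules, -0.197 for activation receptors, 0.124 for naive and quiescence genes, -0.289 for ribosome biogenesis, -0.558 for the interferon response, 0.153 for class IIa deacetylases and MEF2 factors, 0.119 for T cell receptor signalling and 0.312 for CD8 markers. With an estimated correlation 0 of these 9 lists passed (adjusted p of 0.48 to 0.59). Celsr1, a cadherin, and Fcer2a, the low-affinity IgE receptor, had effects of opposite sign in the mice of the 2 genotypes, with differences that did not pass without the pairing by mouse (1.12, adjusted p = 0.41, and -0.767, adjusted p = 0.55). With the mouse as a block Celsr1 passed (adjusted p = 0.043), as did another probe set of Fcer2a (-1.25, adjusted p = 0.034). That other probe set changed by 1.3 in wild-type and 0.048 in null cells, so its effects did not have opposite signs. For the first probe set of Fcer2a the mean change in null cells was -0.0372, close to no change, against 0.73 in wild type.

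Null cells rose less on average to antigen, with a ratio of 0.857, and 1 explanation is that fewer T cells responded in the null cultures. If that were the sole cause, every rise on the linear scale would shrink by a common factor, and after this factor was removed 249 of 856 rising genes (29.1%) kept the 3 null mice apart from the 3 wild-type mice, against 10% by chance and 152 in the highest other split of the mice. A made-up table with a common factor of 0.8 gave 7.54%. The highest other split of the real mice gave 17.8%, so neither 7.54% nor 10% is a fair baseline. The real split was the highest of 10, which are too few splits to judge the share by. Fewer responders as the sole cause was thus left open. A second explanation is that a larger share of B cells diluted T cell RNA, since B cell markers were higher in null cells by a median of 0.65 without antigen. T cell receptor signalling genes would then be lower in unstimulated null cells by about the -0.374 by which the 59 strongly induced genes differed. The signalling genes had a median difference of 0.0216 (SD 0.155 over 22 genes), without such a fall. CD8 markers went the other way, with a median of -0.121 and 3 of 4 lower (camera adjusted p = 0.59). Their level was lowest in null replicate 2 (9.967, against 10.42 and 10.44), the null replicate highest in B cell markers. Dilution was therefore left open. Another explanation, weaker transcriptional signalling per cell without PKD2, was not tested.

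Splits of the 3 and 3 arrays of each comparison in all 10 ways are too few to judge the counts by: 1 of 10, the real split, reached the count each time, with 13078 against 53 in the highest other split for stimulation in wild type, 11170 against 0 in null cells, 17 against 2 and 531 against 24 for the genotypes without and with antigen, and 1 against 0 for the difference of the effects. For stimulation, 4 of the 10 splits parted the 2 arrays of all 3 mice, the real one among them, and the others of these gave at most 0 calls in either genotype, while the other 6 parted 1 pair and gave at most 53 and 0.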

How the results depend on the processing

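The choices moved the counts as follows, and the cause was not tested unless it follows from how the alternative was built. For stimulation, 1 probe set per gene gave 6726 calls in wild type and 6057 in null cells, as fewer probe sets entered, and a fold threshold of log2 1 left 4114 and 2807. Leaving out 1 array gave 11401 to 12476 and 9339 to 10705.

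For null against wild type without antigen the count of 17 became 44 with the mouse as a random block, 57 with trend and robust variances (54.4% higher in null cells against 41.2%), 3 with only the groups compared, 32 with quantile normalization (34.4% higher), 55 with 1 probe set per gene (63.6% higher), 11 with the fold threshold (54.5% higher), and 3 to 27 without 1 array, lowest without wild-type replicate 3 and highest without null replicate 2. Alternatives chosen after the values were seen gave 5 without the 3 arrays richest in Krt18, 41 with sex as a covariate and 69 with the B cell marker level as a covariate. With antigen the count of 531 became 91 with only the groups compared, 115 with the fold threshold and 75 to 718 without 1 array, lowest without null replicate 1 and highest without wild-type replicate 1. It was 11 without the Krt18-rich arrays and 1807 with the B cell level as a covariate. Quantile normalization gave 56.8% of the calls higher in null cells, against 67.8%.

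For the difference of the stimulation effects the count of 1 became 43 with the mouse as a fixed block, 0 above the median level, 4 with trend and robust variances, 3 with 1 probe set per gene, 0 without the Krt18-rich arrays, 0 with sex as a covariate, and 0 to 13 without 1 array, lowest for instance without wild-type unstimulated replicate 1 and highest without null stimulated replicate 2. With an estimated correlation camera called 0 lists in each of the 5 comparisons, against 11, 10, 8, 10 and 9 with the preset one. Fry called 12 and 10 lists for stimulation, 2 and 1 for the genotypes without and with antigen, and 0 for the difference. The mean of all probe sets of each gene gave 11, 10, 7, 11 and 7 lists: the 3 calls lost are given beside the results, and erythroid markers with antigen were gained (adjusted p = 0.027). The response ratio stayed between 0.834 and 0.894 for rises and between 0.779 and 0.893 for falls. Of 473 gene results over the 5 comparisons, 243 were called. Of 8454 alternatives of the 473 results, 7987 were the same, 399 weaker, 67 stronger and 1 reversed. These counts include stimulation effects and results that were not called, so they do not measure how well the genotype calls held. The reversed one was Mzb1, a plasma cell gene, which changed with stimulation in wild type by 0.0495 (adjusted p = 0.81) instead of -0.83 with the B cell level as a covariate. With the mouse as a block, stimulation also passed for Inpp4b in wild type (-0.53, adjusted p = 0.03) and for Celsr1 (0.37, adjusted p = 0.015), Ighm (-0.67, adjusted p = 0.00032) and the sex-linked gene Uty (-0.61, adjusted p = 0.023) in null cells. Besides these and the calls given beside the results, the block changed no call of a list or of a gene named by the rule. Camera with a block was not run for the genotype comparisons, and an offset on the linear scale did not apply to log2 values.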

Other observations

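Of the tests below, those of the segment beside Prkd2 and of gland tissue were written before their results were seen, while the salivary gland genes were picked out after their values were seen.

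Ifng and the interferon response genes were followed mouse by mouse, and whether the former drives the latter was not tested. Ifng rose by 5.16, 5.42 and 5.77 in the wild-type mice and by 3.16, 4.33 and 2.45 in the null mice, and the median of the 29 interferon response genes rose by 0.713, 0.722 and 0.924 against 0.0925, 0.363 and 0.225. Null replicate 2 had both the highest Ifng rise and the highest list median among the null mice, while replicates 1 and 3 had the opposite order, and the list was already lower in null cells without antigen (median -0.15). Il2 (6.46, 6.66 and 7.34 against 5.61, 6.31 and 5.45) and Ccl3 (6.78, 7.69 and 6.95 against 5.27, 5.15 and 5.18) also rose more in each wild-type mouse than in each null mouse, and for these 3 genes the difference of the effects did not pass, except Ccl3 with the mouse as a block (adjusted p = 0.034).

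Prkd2 itself fell with antigen in wild-type cells (-1.84, SE 0.148, adjusted p = 9.4e-07), as did its paralog Prkd3 (-0.45, SE 0.141, adjusted p = 0.03); Prkd3 did not change in null cells (0.08, adjusted p = 0.79), and the difference of the effects did not pass (0.53, adjusted p = 0.64). A few strongly induced genes, picked out after their values were seen, rose at least as much in null cells: Tnf, Lta, the transcription repressor Gfi1, the cyclin Ccnd2, the nucleoside transporter Slc29a1 and Tacc2. Erythroid markers, of which Alas2 alone varied much, had mean levels of 5.149 ± 0.584 (SD, n = 3) and 5.004 ± 0.421 in wild-type cells without and with antigen, highest in replicate 2 (5.783 and 5.483), against 4.116 and 4.085 in null cells.

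Slc1a5, the glutamine transporter gene, lies near Prkd2 on chromosome 7, and it was lower in null cells with and without antigen. One explanation is a flanking segment that stayed from another mouse strain when the targeted allele was bred, which would make other neighbours differ too. Of 49 measured neighbours on both sides 11 (22.4%) had an unadjusted p under 0.05 for the genotype difference averaged over both conditions, against 19.6% of 18142 other genes (one-sided Fisher exact p = 0.361, with a confidence interval of the odds ratio of 0.547 to 2.37), which leaves this open. The genes past the adjusted threshold among them were Ccdc61, Dhx34, Hif3a and Sae1, and the stimulation effects on Dhx34 differed with the mouse as a block (0.88, adjusted p = 0.046, and 0.55 without it). The share of neighbours past the adjusted threshold was not compared with that of the other genes. Another explanation is that PKD2 is needed for Slc1a5 transcription: Slc1a5 still rose with antigen in null cells by 1.77, against 1.99 in wild type, and this was not tested further.

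Transcripts of salivary glands were high in some arrays, and carry-over of gland epithelium into lymph node suspensions could account for them, as glands lie next to the cervical nodes. The 3 arrays with the highest Krt18 were also the 3 with the highest median of 15 other epithelial genes, 3 of 3, of which 2 came from the same mouse (replicate 3). The medians were 5.49, 5.74 and 5.76 against 4.15 to 4.49 elsewhere, and Cdh1, the epithelial cadherin gene, stood at 6.984, 8.376 and 7.11. In wild-type replicate 2 the unstimulated array lacked this signal (Krt18 at 6.5) although its stimulated array had it. Bpifa2, a parotid protein gene, was high in null cells too (11.17, 11.62 and 8.024 without antigen), while Dcpp3 stayed between 6.234 and 9.209 in null cells and at 11.82 or more in wild type. Carry-over of gland tissue of a fixed composition would not give these unlike patterns, but the composition was not measured. Strain differences in these secreted proteins were not tested. Amy1 and Smr3a, also genes of salivary glands, were higher in unstimulated null cells (0.978 and 1.08, not called). Amy1 was lowest (2.909) in the wild-type array with the highest Krt18. Among unstimulated arrays, Amy1, Bpifa2, Car6 and Pip were lowest in those of the male mice, and a link to sex was not tested.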
